A study of Mus musculus with 19 samples.

How the data were processed

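Small RNA libraries were made from hippocampal CA1 tissue of wild-type mice, microdissected and snap-frozen, with Illumina TruSeq reagents per the labels. The deposited values are counts, 1 whole number per mature miRNA name and library, which the authors did not normalise. The processing notes of the submitters name CASAVA 1.8.2, cutadapt, STAR, HTSeq and the mm10 build, without order or settings, and the release of the miRNA annotation is not given in the sources used here. Each library listed 1148 miRNAs, 255 of them with no count in any library, and 4 HTSeq summary lines that were all 0 and were left out. The share of unassigned reads is therefore unknown, and the totals are reads assigned to miRNAs. They ranged from 3585489 to 6808281 per library. Reads carry no molecular identifiers, so counts are not independent molecules.

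Groups were taken from the labels: 8 young vehicle, 5 aged vehicle and 6 aged SAHA libraries. The comparisons, their tests, the lists and the rules for naming miRNAs were written before the data were examined. The enrichment test of the Dlk1-Dio3 cluster and several tests of other explanations were chosen afterwards. The labels give neither sex nor sequencing batch, so neither could be tested. All 19 libraries were kept, and no library appeared to be a copy of another: over the 53 pairs within groups, chi-square per degree of freedom was 27.4 to 329 and r of log2 CPM 0.987 to 0.996.

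Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 509 miRNAs and left 639 untested, scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, 1 term per group, common biological coefficient of variation 0.152). A call is a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The standard error of a log2 fold change is its size divided by the square root of F. CPM are from the cpm function of edgeR after TMM scaling, and shares are percent of the raw miRNA counts of a library. For age and SAHA, up to 12 higher and 12 lower calls with the smallest p were named, and where under 20 passed the next by p were given by value only. For aged SAHA against young vehicle 5 per direction were named, together with up to 4 members per list and the 8 most abundant miRNAs.

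The 21 lists fixed beforehand cover cell types and tissues (neuron-enriched, oligodendrocyte and myelin, microglia and immune, astrocyte-enriched in culture, endothelial and mural cells, erythrocyte, choroid plexus and ciliated epithelium, epithelial miR-200 family, sensory miR-183 cluster, Hox cluster), brain processes (synaptic plasticity and memory, brain ageing literature, activity-induced miR-132 and miR-212 cluster), families (let-7, miR-29, miR-30, miR-181, miR-17-92 and paralogous clusters) and loci (Dlk1-Dio3 imprinted cluster, Sfmbt2 intronic cluster, mirtrons). Lists overlap in members. Those with at least 3 tested members were tested with camera on voom values (limma 3.58.1, preset correlation 0.01), with adjustment over lists within a comparison, and beside it with an estimated correlation and with fry. Library summaries were compared by exact two-sided permutation tests with adjustment over 15 tests.

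Precursor positions came from RefSeq for GRCm38 and host genes from GENCODE M21. Of the 1148 names, 1122 matched a precursor and 26 did not, and for names with several precursor loci no position is given here.

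Alternatives were DESeq2 size factors, library size only, no filter, a filter of CPM of 10 in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, only the groups compared, arms and copies summed, the 3 most abundant miRNAs left out, each library left out, and the replicate number as a block. Leaving out aged SAHA 1 and young vehicle 6 together was added after the data were seen. Tested on simulated data with 200 of 509 miRNAs changed, the SAHA comparison recovered 41% of 1.25-fold, 76.6% of 1.5-fold and 94.8% of 2-fold changes, with 2.41% false among its calls. For age these shares were 49.1%, 80.6% and 92.7% (2.82% false), and for aged SAHA against young vehicle 51.6%, 81% and 96.5% (2.68% false). The data gave far fewer calls than 200 (11 for age, 22 for SAHA and 71 for aged SAHA against young vehicle). With fewer true changes the adjusted threshold is harder to pass, so recovery in these data can be lower. The simulated miRNAs were also drawn independently of each other.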

Results

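Small RNA was sequenced from the hippocampal CA1 subregion of wild-type mice of the strain labelled C57B/6JRj. The 19 libraries fell into 3 groups, with 8 libraries from animals of 3 months given vehicle, 5 from animals of 20 months given vehicle and 6 from animals of 20 months given SAHA. SAHA (vorinostat) is an inhibitor of histone deacetylases, and it was given by mouth at 0.67 g per L of water that also held 18 g per L of cyclodextrin, the vehicle. The aged animals were treated for 4 weeks, and the duration for the young animals is not given in the sources used here. Reads assigned to miRNAs totalled 3585489 to 6808281 per young vehicle library, 4642434 to 5249168 per aged vehicle library and 4211365 to 5410804 per aged SAHA library. Between 680 and 735 miRNAs had at least 1 count in a young vehicle library, 700 to 712 in an aged vehicle library and 702 to 734 in an aged SAHA library.

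The most abundant miRNA was miR-127-3p, with 13.8% ± 1.57 of all miRNA counts (SD, n = 19), followed by miR-181a-5p with 13.6% ± 1.45 and miR-26a-5p with 7.59% ± 0.534. The next 5 were miR-22-3p with 4.64%, miR-9-5p with 3.86%, let-7f-5p with 3.57%, miR-30a-5p with 3.32% and miR-128-3p with 3.18% of counts. The share of miR-127-3p was 12.1% ± 0.713 in aged SAHA (SD, n = 6) and 14.7% ± 1.07 in young vehicle (SD, n = 8), a difference with an exact two-sided permutation p of 0.000666 and a Benjamini-Hochberg adjusted value of 0.00999 over 15 tests of library summaries. Against aged vehicle, where the share was 14.4% ± 1.40 (SD, n = 5), the exact permutation p was 0.0152 and the adjusted value 0.114. No other summary passed the adjusted threshold: total counts, detected miRNAs and the share of the 10 most abundant miRNAs had adjusted values from 0.137 to 0.944 by the same exact permutation tests.

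The first comparison asks which CA1 miRNAs differed between animals of 20 and 3 months, both given vehicle. miR-146a-5p, a feedback inhibitor of inflammatory NF-kB signalling, rose with age from 396 ± 54.4 to 687 ± 111 CPM (counts scaled to library size; mean ± SD, 8 young and 5 aged libraries), a log2 fold change of 0.80 ± 0.17 (SE), and all 5 aged libraries lay above all 8 young ones. 3 products of the neighbouring X-linked precursors Mir351 and Mir322 fell, with log2 fold changes of -0.82 ± 0.12 for miR-351-5p, -0.52 ± 0.10 for miR-322-5p and -0.69 ± 0.17 for miR-322-3p. A pair of neighbouring precursors on chromosome 2, Mir298 and Mir296, gave lower miR-298-5p (-0.89 ± 0.14, from 376 to 204 CPM) and lower miR-296-5p (-0.90 ± 0.17, from 8.87 to 4.76 CPM). Both arms of the precursor Mir181c fell, miR-181c-5p by 0.42 ± 0.07 and miR-181c-3p by 0.29 ± 0.06 on the log2 scale. miR-150-5p, a miRNA abundant in lymphocytes, fell by 0.36 ± 0.07 on that scale, from 687 ± 20.0 to 535 ± 26.5 CPM, and miR-135b-5p and miR-490-3p fell by 0.68 ± 0.16 and 0.43 ± 0.11.

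These 11 miRNAs, 1 higher and 10 lower in aged animals, were those with an adjusted p under 0.05 by the edgeR quasi-likelihood test among 509 tested, where 80 had an unadjusted p under 0.05. The adjusted p was 0.00938 for miR-146a-5p, 0.000386 for miR-351-5p, 0.000776 for miR-298-5p, 0.00154 for miR-181c-5p and 0.00223 for miR-150-5p. It was 0.0026 for both miR-296-5p and miR-322-5p, 0.00445 for miR-181c-3p, 0.0134 for miR-135b-5p, 0.0238 for miR-322-3p and 0.0259 for miR-490-3p. All 5 aged libraries lay below all 8 young ones for 7 of the lower miRNAs, and 4 of 5 did for miR-135b-5p, miR-322-3p and miR-490-3p. With 1 library left out, the calls of miR-135b-5p (highest adjusted p 0.0967, without aged vehicle 3 or 4), miR-322-3p (0.108, without aged vehicle 1, 3, 4 or 5) and miR-490-3p (0.141, without aged vehicle 2, 3 or 4 or young vehicle 1 or 3) ended. That of miR-490-3p also ended with the 3 most abundant miRNAs left out. Leaving out aged SAHA 1 and young vehicle 6, which stood apart from their groups, gave 18 calls, a choice made after the data were seen, and DESeq2, limma-voom and a fit of only the groups compared gave 20, 26 and 19.

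In the GRCm38 (mm10) build, the RefSeq precursor of miR-146a-5p lies on chromosome 11 from 43374397 to 43374461, outside the genes of the GENCODE annotation. Mir351 spans 53053255 to 53053353 and Mir322 spans 53054255 to 53054349 on chromosome X, and Mir296 and Mir298 span 174267047 to 174267125 and 174267504 to 174267585 on chromosome 2, all of them intergenic. The miR-150-5p precursor is intergenic on chromosome 7, from 45121757 to 45121821. Mir181c lies in an intron of Nanos3 on chromosome 8 (84178873 to 84178961), Mir490 in an intron of Chrm2 on chromosome 6 (36421742 to 36421825) and Mir135b in an intron of AC124108.1 on chromosome 1 (132198088 to 132198184).

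**Figure D1:**
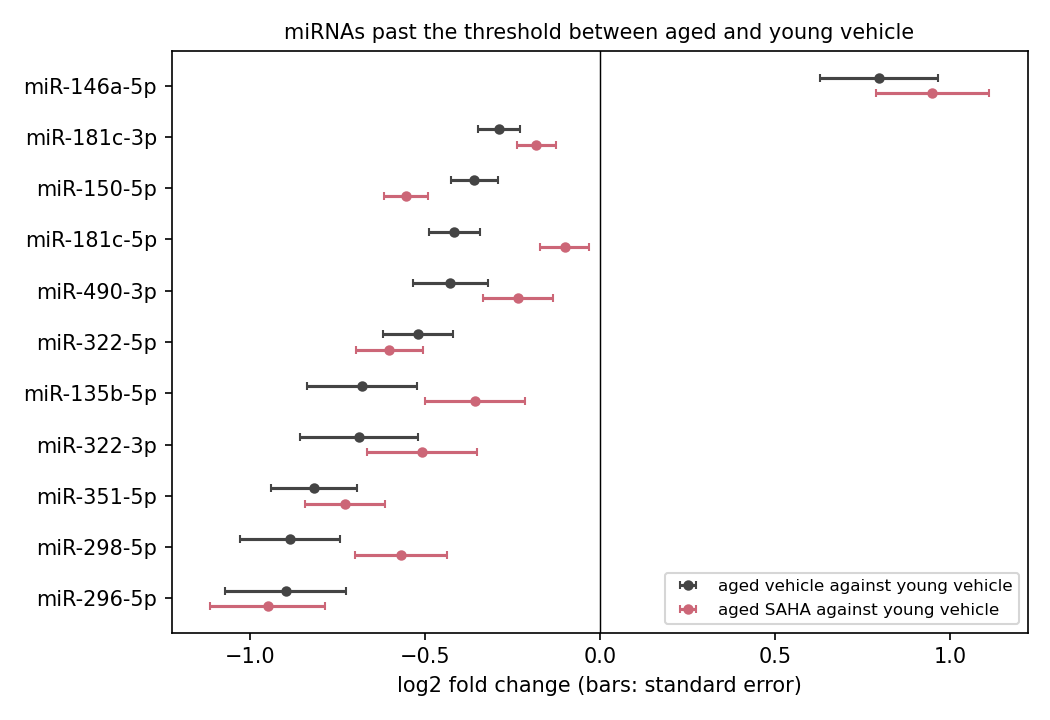
Log2 fold changes against young vehicle (x axis; bars are standard errors) of the 11 miRNAs past the threshold between aged and young vehicle (y axis), in aged vehicle (5 libraries, grey) and in aged SAHA (6 libraries, red), each against 8 young vehicle libraries. All 11 have the same sign in both, with miR-146a-5p at 0.80 and 0.95 and miR-351-5p at -0.82 and -0.73.

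The next 9 miRNAs by p did not pass the threshold (adjusted p from 0.0621 to 0.0796 by edgeR). Their log2 fold changes were -0.79 ± 0.21 for miR-669a-3p, -0.39 ± 0.11 for miR-148b-5p, -0.20 ± 0.06 for miR-181d-5p, -0.95 ± 0.27 for miR-542-3p and 0.40 ± 0.12 for miR-384-5p. For miR-144-5p, miR-10a-5p and miR-296-3p they were -0.54 ± 0.16, 0.88 ± 0.26 and -0.89 ± 0.27. miR-5109 had a value of 1.58 ± 0.44, with 103 CPM in aged vehicle 3 and 12.8 to 22.3 CPM in the other 4 aged vehicle libraries.

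Among the lists of related miRNAs fixed before the data were examined, 5 were called for age by camera, 1 with higher and 4 with lower values in aged animals, and none of these calls held with an estimated correlation. The miR-29 family was called higher as a list (adjusted p = 0.00195, and adjusted p = 0.258 with an estimated correlation). All 7 tested members had positive values with a median of 0.20, miR-29c-3p (0.20 ± 0.06) and miR-29a-5p (0.28 ± 0.11) among them, and 0 passed the threshold over all tested miRNAs by edgeR while 5 did when adjusted over the list alone. The Sfmbt2 intronic cluster was called lower as a list (adjusted p = 0.00195, and adjusted p = 0.258 with an estimated correlation). Only 6 of its 80 miRNAs were tested, and with the filter of CPM of 10 in 5 libraries too few were left to test the list. Its member miR-467a-5p was at 6.52 to 9.81 CPM in the young vehicle libraries. Its 6 tested members had negative values (median -0.50), such as -0.79 ± 0.21 for miR-669a-3p, -0.74 ± 0.23 for miR-669c-5p and -0.48 ± 0.16 for miR-467a-5p, with 0 passing over all tested and 4 lower when adjusted over the list alone. The epithelial miR-200 family was called lower as a list (adjusted p = 0.00865, and adjusted p = 0.258 with an estimated correlation). Its 5 tested members had negative values (median -0.37), with miR-429-3p at -0.42 ± 0.13 and miR-200b-3p at -0.37 ± 0.13, of which 0 passed over all tested and 3 were lower when adjusted over the list alone. The erythrocyte list (5 of 5 negative, median -0.28) was called lower with adjusted p = 0.0341, and adjusted p = 0.362 with an estimated correlation. Its members miR-144-5p and miR-451 had values of -0.54 ± 0.16 and -0.29 ± 0.14, with 0 passing over all tested and 1 lower when adjusted over the list alone. The miR-181 family (5 of 8 negative, median -0.17) was called lower with adjusted p = 0.0413, and adjusted p = 0.588 with an estimated correlation. It had 2 members lower over all tested, both arms of miR-181c, and 3 when adjusted over the list alone. The self-contained fry test, which asks only whether members move 1 way on balance, gave 0.0166 for the miR-29 and Sfmbt2 lists, 0.0268 for miR-200, 0.0674 for erythrocyte and 0.0679 for miR-181.

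Leaving out aged vehicle 3 or 4 or young vehicle 2, 4 or 6 ended the calls of the erythrocyte list (highest adjusted p 0.0896, without aged vehicle 4) and the miR-181 family (0.104, without young vehicle 2), and leaving out aged vehicle 1 or 5 or young vehicle 3 ended that of miR-181 alone (0.0569, 0.0834 and 0.0537). Summing arms and copies of a miRNA ended the erythrocyte call (0.158), and fitting only the groups compared ended that of miR-181 (0.0814).

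The other 14 tested lists were not called for age by camera. Adjusted p was 0.596 for neuron-enriched miRNAs (0 of 26 called), 0.593 for synaptic plasticity and memory (2 of 23 lower, both arms of miR-181c), 0.494 for oligodendrocyte and myelin (0 of 7), 0.418 for microglia and immune (miR-146a-5p higher and miR-150-5p lower, of 10) and 0.887 for astrocyte-enriched in culture (0 of 4) and for endothelial and mural cells (0 of 11). It was 0.932 for choroid plexus and ciliated epithelium (0 of 12), 0.593 for brain ageing literature (1 of 24 higher, miR-146a-5p) and for the let-7 family (0 of 21), 0.822 for the miR-30 family (0 of 11) and 0.789 for the miR-17-92 and paralogous clusters (0 of 14). For the Dlk1-Dio3 imprinted cluster it was 0.705 (0 of 82), for the activity-induced miR-132 and miR-212 cluster 0.903 (0 of 4) and for mirtrons 0.596 (0 of 10). Adjusted over the list alone, miR-10a-5p was higher in the endothelial list, and 1 member was higher in the astrocyte list. The brain ageing list had 2 higher and 1 lower that way. Median and mean differed in sign for the astrocyte list (-0.02 and 0.13, test up), the brain ageing list (-0.02 and 0.03, test up), the miR-30 family (-0.01 and 0.03, test up) and the miR-132 and miR-212 cluster (8.43e-05 and -0.000344, test up). The sensory miR-183 cluster and the Hox cluster had 2 tested members each and were not tested, with median log2 fold changes of 0.02 and -0.07.

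The SAHA comparison asks which miRNAs differed between aged animals given SAHA and aged animals given vehicle (6 and 5 libraries). miR-128-3p, a brain-enriched miRNA among the 8 most abundant here, fell from 34553 ± 3222 to 25447 ± 2299 CPM (mean ± SD), a log2 fold change of -0.44 ± 0.08 (SE) with all 6 SAHA libraries below all 5 vehicle libraries. miRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12 made up 8 of the 16 that fell, among them the most abundant of all, miR-127-3p, from 142974 ± 13656 to 119061 ± 7901 CPM (-0.26 ± 0.07). The largest rises among the 6 that passed were in miR-1a-3p, a muscle miRNA present here at 3.53 to 7.05 CPM on average (0.99 ± 0.25), and miR-148b-5p (0.65 ± 0.12, from 21.5 to 34.0 CPM). The arms of the let-7d precursor moved apart, with let-7d-5p rising by 0.33 ± 0.07 and let-7d-3p falling (-0.37 ± 0.08). miR-181c-5p, which fell with age, rose under SAHA from 3881 ± 336 to 4827 ± 370 CPM (0.31 ± 0.08, all 6 SAHA libraries above all 5 vehicle libraries).

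edgeR called 6 miRNAs higher and 16 lower of 509, where 99 had an unadjusted p under 0.05. Beside those above, miR-106b-5p (0.38 ± 0.09) and miR-1839-5p (0.34 ± 0.09) rose. Falls outside the cluster were -0.62 ± 0.11 for miR-345-3p, -0.58 ± 0.10 for miR-301b-3p, -0.42 ± 0.09 for miR-222-3p and -0.28 ± 0.07 for miR-9-3p, the last a neuronal miRNA. miR-1983, named after its values were seen, fell too (-0.33 ± 0.08, adjusted p 0.0229). Adjusted p was 0.00201 for miR-148b-5p, miR-345-3p and miR-301b-3p, 0.00344 for miR-128-3p, 0.00937 for let-7d-5p and miR-222-3p and 0.0124 for let-7d-3p. For miR-106b-5p, miR-181c-5p and miR-9-3p it was 0.0176, for miR-1a-3p and miR-127-3p 0.0217 and for miR-1839-5p 0.0267. Scaling changed the balance of directions but not the direction of a call named here: 10 rose and 16 fell with DESeq2 size factors, 11 and 16 with library size alone and 6 and 12 with the 3 most abundant miRNAs left out.

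The count was 13 without aged vehicle 1, 14 without aged vehicle 3 and 11 without aged SAHA 6, and it was 37 without aged SAHA 1 and young vehicle 6, a choice made after the data were seen. DESeq2 gave 42, limma-voom 47 and summed arms 9. Leaving out 1 library ended several of the calls. They were those of miR-1a-3p (highest adjusted p 0.0761, without aged vehicle 1, 3, 4 or 5 or aged SAHA 6), miR-1839-5p (0.074, without aged vehicle 1 or 3 or aged SAHA 2, 5 or 6), miR-181c-5p (0.0737, without aged vehicle 1 or aged SAHA 6), miR-106b-5p and miR-9-3p (both 0.0531, without aged vehicle 3 or aged SAHA 6), miR-1983 (0.0737, without aged vehicle 1, 3 or 5 or aged SAHA 3 or 6) and miR-127-3p (0.0793, without aged vehicle 1, 4 or 5 or aged SAHA 3 or 6). Fitting only the groups compared ended those of miR-127-3p, miR-9-3p, miR-1983, miR-496-3p, miR-153-5p and miR-1193-3p. Having no low-count filter ended the last 4 of these, and leaving out the 3 most abundant miRNAs the last 3.

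Of the 82 tested miRNAs of the Dlk1-Dio3 cluster, 8 fell and none rose over all tested, where 2.58 lower calls would be expected from the cluster's share of tested miRNAs (Fisher's exact test, two-sided p = 0.00141, odds ratio 5.63). This enrichment test was chosen after the calls were seen. It takes the 82 miRNAs as independent, while their estimated correlation was 0.26, so its p can be too small. Adjusted over the list alone, 9 were lower. Falls were -0.53 ± 0.11 for miR-379-3p (adjusted p 0.0042), -0.50 ± 0.10 for miR-485-3p (0.00439), -0.37 ± 0.08 for miR-673-5p (0.00937), -0.70 ± 0.17 for miR-539-5p (0.0164) and -0.55 ± 0.14 for miR-409-5p (0.0211). miR-496-3p (-0.35 ± 0.10) and miR-1193-3p (-0.76 ± 0.21), named after their values were seen, both had an adjusted p of 0.0368. The cluster as a whole was not called by camera (adjusted p = 0.707, and adjusted p = 0.985 with an estimated correlation). Its median was 0.02 and its mean -0.04, and 44 of its 82 values were positive. Leaving out 1 library ended the calls of miR-409-5p (highest adjusted p 0.0852, without aged vehicle 1 or 4 or aged SAHA 3 or 6), miR-539-5p (0.0531, without aged vehicle 3), miR-496-3p (0.0793, without any aged vehicle library or aged SAHA 1, 3, 4 or 6) and miR-1193-3p (0.143, without aged vehicle 1, 2, 3 or 4 or aged SAHA 2, 3 or 6).

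The tested precursors of the cluster span 109563692 to 109747960 on chromosome 12 (GRCm38). Mir127 lies at 109592846 to 109592915, Mir379 at 109709060 to 109709125 and Mir673 at 109571990 to 109572080, all intergenic in GENCODE, and Mir485 lies in an exon of the noncoding host gene Mirg at 109734902 to 109734974. The let-7d precursor lies on chromosome 13 from 48536012 to 48536114, in an exon of 6720427I07Rik, and the miR-148b precursor on chromosome 15 from 103285125 to 103285221, in an intron of Copz1. For miR-128-3p, miR-9-3p and miR-1a-3p more than 1 precursor locus can give the mature sequence, so no single position applies.

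**Figure D2:**
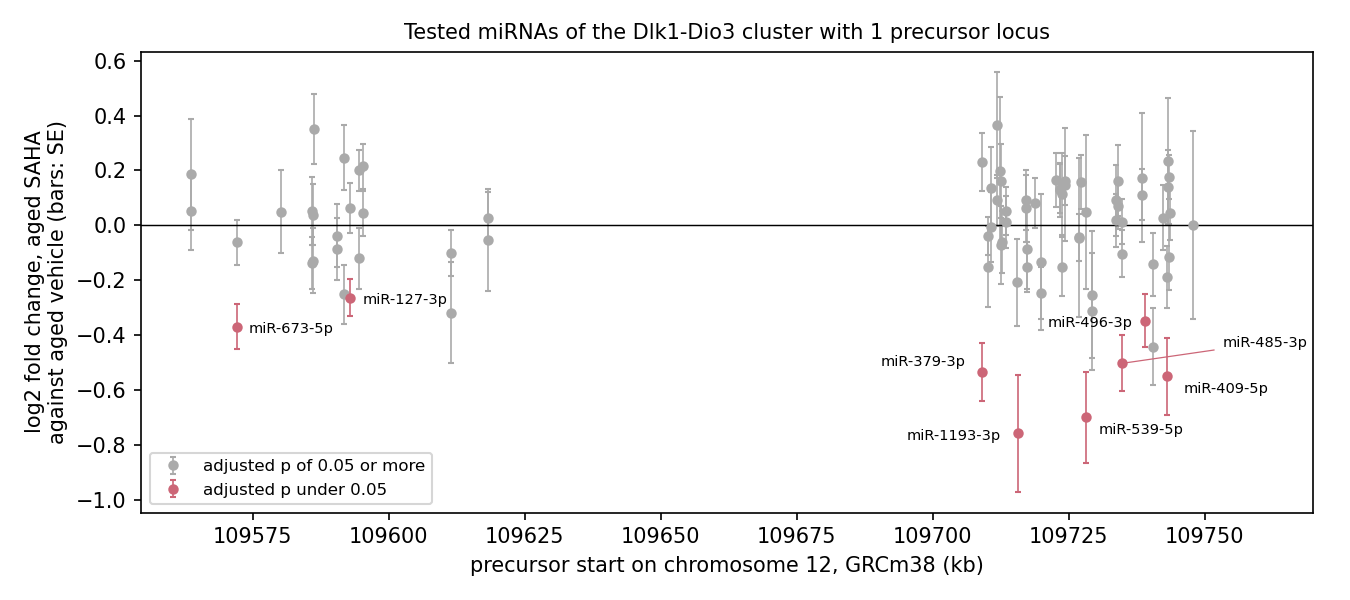
Log2 fold change of aged SAHA against aged vehicle (y axis; bars are standard errors, 6 and 5 libraries) of the 82 tested Dlk1-Dio3 miRNAs by the start of their precursor on chromosome 12 in kb (x axis). The 8 named points in red had an adjusted p under 0.05, all with values below 0, and the grey points did not.

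Of the 21 lists, 1 was called for SAHA: neuron-enriched miRNAs were lower by camera (adjusted p = 0.0460, median -0.07, 19 of 26 negative), and adjusted p = 0.936 with an estimated correlation. Over all tested and adjusted over the list alone, 3 members fell, namely miR-128-3p, miR-9-3p and miR-153-5p (-0.38 ± 0.11, adjusted p 0.0368), while miR-124-5p had a value of -0.26 ± 0.09 (adjusted p 0.0882). The call of miR-153-5p ended without aged vehicle 1, 2, 3 or 5 or aged SAHA 3 or 6 (highest adjusted p 0.116). fry gave 0.426 for the list, and its test for change in either direction gave 0.00713. The list's call also ended with DESeq2 size factors (0.0604), only the groups compared (0.055) or summed arms (0.193), and without aged SAHA 1 (0.462) or 3 (0.288) or aged vehicle 1 (0.121), 3 (0.181) or 5 (0.062).

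In the libraries themselves, mean log2 CPM of the neuron-enriched list relative to all 19 libraries was -0.20 in aged SAHA 1 and -0.23 in aged SAHA 3, against -0.07 to 0.06 in the other 4 SAHA libraries. Aged SAHA 1 also had the highest oligodendrocyte (0.72) and microglia (0.88) values of all libraries, and endothelial values were 0.89 in aged SAHA 1 and 0.91 in aged SAHA 3. Aged vehicle 2 stood apart as well, with an endothelial value of 0.62 against -0.41 to -0.24 in the other 4 aged vehicle libraries. For SAHA against aged vehicle those lists had camera adjusted p of 0.266 (oligodendrocyte, median 0.18; miR-219-2-3p at 0.44 ± 0.15), 0.691 (microglia, median 0.23; miR-155-5p at 0.87 ± 0.33 and miR-150-5p at -0.20 ± 0.07) and 0.266 (endothelial, median 0.31). Adjusted over the list alone, 1 oligodendrocyte member and 1 erythrocyte member were higher. The erythrocyte list, with miR-144-5p at 0.55 ± 0.17, had a median of -0.05 and a mean of 0.12 (adjusted p 0.707, test up). The other lists had adjusted p from 0.266 to 0.975. Median and mean differed in sign for the synaptic list (0.01 and -0.01, test down), the choroid plexus list (0.07 and -0.00267, test up), the miR-200 family (-0.09 and 0.01, test down), the let-7 family (0.02 and -0.02, test down) and the miR-30 family (-0.01 and 0.01, test up).

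**Figure D3:**
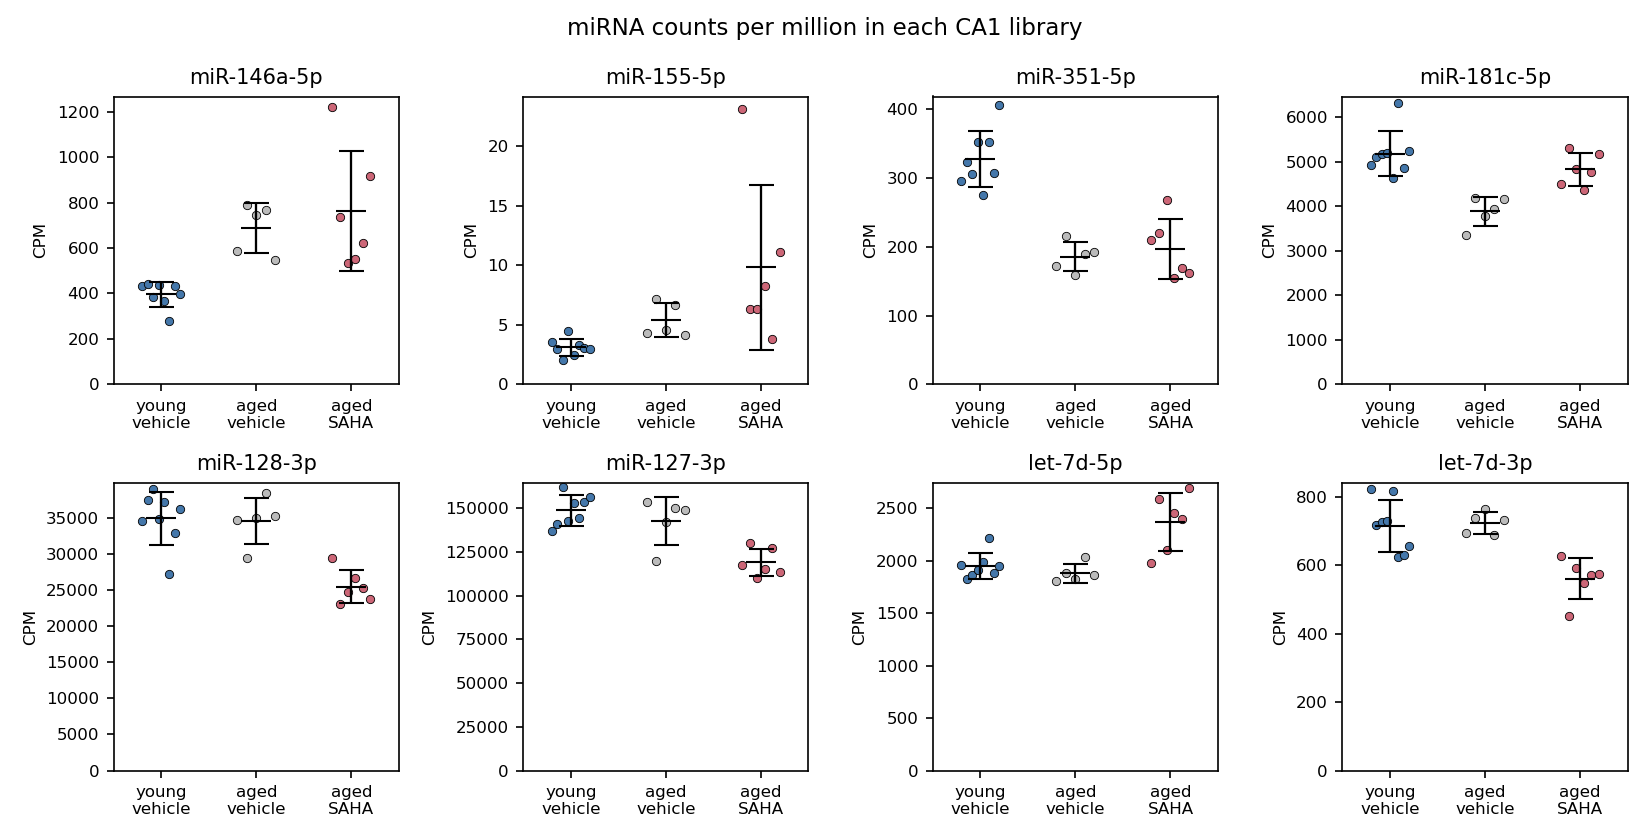
CPM (y axes, from 0) of 8 miRNAs in each library by group (x axes), with the mean and SD of 8 young vehicle, 5 aged vehicle and 6 aged SAHA libraries as bars. miR-128-3p averaged 34925, 34553 and 25447 CPM in these groups, and miR-146a-5p averaged 396, 687 and 764 CPM.

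The comparison of aged SAHA with young vehicle (6 and 8 libraries) shows which differences from young animals were present in treated aged animals, where age and drug both differ. miR-155-5p and miR-146a-5p, both induced in activated immune cells, rose by 1.68 ± 0.31 and 0.95 ± 0.16 on the log2 scale, to 9.82 ± 6.95 and 764 ± 265 CPM (SD). Without aged SAHA 1, which had the highest level of both, these values were 1.21 ± 0.22 and 0.76 ± 0.13, with adjusted p of 0.000783 and 0.000596 by edgeR. miR-10a-5p (1.35 ± 0.25), the hypoxia-induced miR-210-3p (0.67 ± 0.14) and miR-339-5p (0.46 ± 0.08) also rose. miR-150-5p fell from 687 ± 20.0 to 468 ± 52.0 CPM (-0.56 ± 0.06), and miR-351-5p (-0.73 ± 0.11), miR-322-5p (-0.60 ± 0.10), miR-429-3p (-0.79 ± 0.13) and miR-673-5p (-0.48 ± 0.07) fell too.

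edgeR called 27 miRNAs higher and 44 lower, and 167 had an unadjusted p under 0.05. With DESeq2 size factors these were 38 and 42, with library size alone 51 and 33, and without the 3 most abundant miRNAs 38 and 36, so which direction held more calls depended on the scaling. Adjusted p was 4.42e-06 for miR-150-5p, 0.000238 for miR-673-5p, miR-351-5p and miR-322-5p, 0.000244 for miR-429-3p, 0.000479 for miR-339-5p, 0.000508 for miR-146a-5p, 0.000776 for miR-155-5p, 0.00118 for miR-10a-5p and 0.00218 for miR-210-3p. All 6 SAHA libraries lay beyond all 8 young ones for 7 of these 10, and 5 of 6 did for miR-155-5p, miR-210-3p and miR-429-3p. The miR-155 precursor lies in an exon of Mir155hg on chromosome 16, from 84714140 to 84714204, and that of miR-10a-5p is intergenic on chromosome 11, from 96317165 to 96317274 (GRCm38, GENCODE).

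The Sfmbt2 cluster was the list called here by camera (6 of 6 negative, median -0.72, adjusted p = 0.0123), and adjusted p = 0.626 with an estimated correlation. Of its 6 tested members 3 fell, miR-669a-3p by 1.03 ± 0.21, miR-467a-5p by 0.69 ± 0.16 and miR-669c-5p by 0.78 ± 0.21 on the log2 scale, and 4 were lower when adjusted over the list alone. fry gave 0.00136 for this list. It gave 0.0257 for the miR-200 family and 0.0487 for mirtrons, which camera did not call (adjusted p 0.0736 and 0.270, and adjusted p = 0.627 with an estimated correlation for both). The call of miR-669c-5p ended without aged SAHA 5 (adjusted p 0.0544). Aged SAHA 1, with its high microglia and oligodendrocyte values, is in this comparison too. In the microglia and immune list 4 of 10 rose, miR-146b-5p (0.47 ± 0.12) and miR-142-5p (0.49 ± 0.13) beside the pair above, and 1 fell, with 6 higher and 2 lower when adjusted over the list alone (camera adjusted p 0.0736). Without aged SAHA 1, miR-142-5p had a value of 0.29 ± 0.09 (adjusted p 0.0315). In the oligodendrocyte list 2 of 7 rose, miR-219-2-3p (0.61 ± 0.13) and miR-32-5p (0.44 ± 0.14), and 4 when adjusted over the list alone (camera adjusted p 0.0653). The call of miR-32-5p ended without aged SAHA 1 or 6 or young vehicle 1, 3, 4 or 6 (highest adjusted p 0.102) and by limma-voom. The remaining lists had camera adjusted p from 0.0653 to 0.984, and the test's direction (up) differed from the sign of both median and mean for the choroid plexus list (-0.07 and -0.07) and the miR-17-92 list (-0.04 and -0.00884).

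All 11 miRNAs that differed between aged and young vehicle had the same sign in aged SAHA against young vehicle, and 8 passed the threshold there. They were miR-146a-5p, higher, and miR-150-5p, miR-181c-3p, miR-296-5p, miR-298-5p, miR-322-3p, miR-322-5p and miR-351-5p, lower. Both comparisons use the same 8 young vehicle libraries, which alone makes their values alike: their log2 fold changes had a Pearson r of 0.6254 across miRNAs, against a mean of 0.397 (SD 0.0692, from 0.194 to 0.540) in simulated unchanged groups that share those libraries. The simulated miRNAs, here and below, were drawn independently of each other. Members of lists were correlated in the data (0.26 for the Dlk1-Dio3 cluster), so the simulated spread can be too narrow. The 0.6254 therefore cannot show a likeness beyond the shared libraries. The miR-181c-3p call in aged SAHA against young vehicle ended without young vehicle 3 or aged SAHA 4 or 5 (highest adjusted p 0.124), with library size alone, with no filter, with only the groups compared, without the 3 most abundant miRNAs and without aged SAHA 1 and young vehicle 6. That of miR-322-3p ended without young vehicle 4 or 8 or aged SAHA 1, 2, 4, 5 or 6 (highest adjusted p 0.0937), with library size alone and with only the groups compared. miR-181c-5p was the 1 miRNA called lower with age and higher under SAHA. The age and SAHA comparisons share the aged vehicle libraries: their log2 fold changes had a Pearson r of -0.329 and a Spearman rho of -0.297 across 509 miRNAs, which are not independent replicates, while simulated unchanged groups sharing the aged vehicle libraries gave a mean r of -0.581 (SD 0.0472). The covariance was -0.0221 against -0.0202 simulated (SD 0.00305). With separate aged vehicle libraries for each comparison, over 20 splits into 2 and 3 libraries, the median r was 0.0557 (from -0.172 to 0.163) and the median rho -0.0240. A correlation more negative than shared libraries alone give was not seen. Differences particular to either comparison weaken r, so r set against the simulation cannot exclude a reversal of some miRNAs.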

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

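The tests of the Dlk1-Dio3 pattern, of blood in the aged SAHA samples and of the arms of a precursor, the fit without aged SAHA 1 and young vehicle 6, the repeats of tests on lists without each library and the enrichment of the cluster among lower calls were chosen only after the result was seen.

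Single libraries lay far from the rest of their group in 23 of 198 groups of values tested for this, where chance gives about 1 in 20, or 9.9. Young vehicle 6 accounted for 10 of them, aged vehicle 2 and aged SAHA 3 for 3 each, aged SAHA 1 and young vehicle 8 for 2 each, and aged SAHA 6, aged vehicle 3 and young vehicle 5 for 1 each. In young vehicle 6, CPM was low for miR-146a-5p (278.8), miR-384-5p (304), miR-379-3p (119.9) and miR-146b-5p (282). It was high there for miR-181c-5p (6315), miR-181a-5p (175152), miR-9-5p (51186), let-7d-5p (2218), miR-1839-5p (615) and miR-142-5p (391). Young vehicle 8 was high in miR-298-5p (639 CPM) and miR-296-5p (13.5 CPM), and young vehicle 5 was low in miR-467a-5p (6.52 CPM). Aged SAHA 3 was high in miR-322-3p (36.7 CPM) and miR-542-3p (10.4 CPM) and low in miR-26a-5p (68231 CPM). Aged SAHA 1 was high in miR-142-5p (729 CPM) and miR-32-5p (24.1 CPM), and aged SAHA 6 was low in miR-153-5p (46.9 CPM). In aged vehicle 2 the 10 most abundant miRNAs took 56.9% of counts, against 59.4% to 59.9% in the others of its group, and miR-542-3p (5.59 CPM) and miR-146b-5p (656 CPM) were high. miR-5109 was at 103 CPM in aged vehicle 3, against 12.8 to 22.3 in the others of its group.

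The numbers of calls were compared with those from 100 splits of the libraries into groups of the same sizes, the real split included. For age, 1 of 100 splits gave as many as the real 11, namely the real one, and the highest of the others was 3. For SAHA in aged animals 2 of 100 gave as many as the real 22, and the highest of the others was 26. For aged SAHA against young vehicle 1 of 100 gave as many as the real 71, and the highest of the others was 20. The share of splits with as many calls was under 0.05 in all 3 comparisons, without adjustment over the 3. The SAHA split with 26 calls set the 5 vehicle libraries and 1 SAHA library against the other 5 SAHA libraries, which is the real contrast with 1 library moved.

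The 8 Dlk1-Dio3 miRNAs that fell under SAHA had a median log2 fold change of -0.52, while the median of all 82 tested members was 0.0163 (bootstrap 95% interval -0.06 to 0.05). With 1 library left out, the median of all members ran from -0.0265 (aged vehicle 2) to 0.0403 (aged SAHA 1), which argues against lower output of the whole cluster. The bootstrap intervals here and below resample the miRNAs of a list, not the libraries, so they hold no spread between animals. An earlier form of this pattern, in which the whole cluster was lower, failed on the median of all members and was given up together with a test on abundant miRNAs. Without aged SAHA 1 the median of the 8 was -0.512, so their fall did not rest on that library alone, though the 8 were picked with it included. The neuron-enriched list had a median of -0.0745 (interval -0.18 to -0.02, 26 members), a lesser fall, and the neuron score was low in aged SAHA 1 and 3. The bound set for a smaller share of neurons came from the 8, which were picked for their fall in these same data. This test therefore cannot decide on a modest loss of neurons. That list was called lower by camera (adjusted p = 0.0460), though not with an estimated correlation (adjusted p = 0.936). The other tested arms of the precursors of the 8 were not called. They had values of 0.23 ± 0.11 for miR-379-5p, 0.06 ± 0.09 for miR-127-5p, 0.05 ± 0.28 for miR-539-3p and 0.01 ± 0.08 for miR-485-5p. For miR-673-3p and miR-409-3p they were -0.06 ± 0.08 and -0.19 ± 0.11. What remains open is a treatment effect on single arms of some members, as a hypothesis, and a modest loss of neurons. Any unrecorded batch, which the labels do not allow to be tested, remains open too.

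The X-linked cluster of miR-322, miR-351, miR-503, miR-542 and miR-450 had 6 tested miRNAs, none of them from miR-503. All 6 were negative for age (median -0.64) and in aged SAHA against young vehicle (median -0.39), with 3 called in each. The other 41 tested X-linked miRNAs had a median of -0.000242, which argues against a general difference of X-linked miRNAs. The interval of their difference from the cluster was 0.373 to 0.886. This cluster was picked for its fall in these same data, so intervals of the difference from it, here and below, add little. The endothelial and mural cell list had a median of -0.107 (interval of the difference 0.283 to 0.770, 11 members), but aged vehicle 2, whose endothelial score was 0.62 against -0.41 to -0.24 in the other 4 of its group, carries much of this. Without it the list median of -0.323 lay close to the bound of -0.342 that the explanation would need (interval of the difference 0.0240 to 0.743). In aged vehicle 2, miR-542-3p was also high, at 5.59 CPM against 1.96 to 3.00 in the others of its group. In aged SAHA 3, with an endothelial score of 0.91, miR-542-3p was at 10.4 CPM (others 3.17 to 5.78) and miR-322-3p at 36.7 CPM (others 15.9 to 22.7). Aged SAHA 1, with a score of 0.89, was among those others. More vascular tissue in the young samples therefore stays open. Lower expression of this cluster with age is a candidate explanation, found and examined on the same libraries, and sex of the animals, which the labels do not give, was not tested.

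For higher miR-146a-5p and miR-155-5p in aged SAHA than young vehicle, the erythrocyte list with miR-150-5p had a median log2 fold change of -0.274 (interval -0.48 to -0.00643, 6 miRNAs). miR-150-5p, itself called lower in this comparison, was added after the values were seen. The erythrocyte list alone had a median of -0.22, with values from -0.40 to 0.00698. This argues against more blood, though only weakly, since without aged SAHA 5 the interval with miR-150-5p reached 0.0922. The 5 tested arms of miR-142, miR-223 and miR-21, chosen in advance from the microglia and immune list without miR-146b-5p (0.47) and the arms of miR-150 (-0.56 and -0.74), had a median of 0.321 (interval 0.28 to 0.63), and 0.47 or more is what more microglia would need. That interval holds 0.47, so more microglia cannot be told apart from higher levels per cell. Without aged SAHA 1, where the microglia score was 0.88, both miRNAs still passed the threshold at 0.76 and 1.21. miR-146a-5p was also called higher in aged vehicle than in young vehicle, though not with replicate number as a block, and it was not called for SAHA. A rise of it was thus present without the drug. miR-155-5p was called neither for age nor for SAHA, so for it age and drug, which both differ between these groups, stay open.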

How the results depend on the processing

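Leaving out aged SAHA 1 and young vehicle 6 together was chosen only after the result was seen, and all other settings here were planned. The cause of each change was not tested, except that fewer libraries or fewer miRNAs follow from a setting's own construction. The 11 age calls became 20 with DESeq2, 26 with voom, 19 with only the groups compared and 18 without that pair of libraries, and 8 to 14 with 1 library left out. All 11 were among the calls of each of the first 4 settings. The 22 SAHA calls became 42 with DESeq2, 47 with voom, 9 with summed arms and 37 without the pair, and 11 (without aged SAHA 6) to 33 (without aged SAHA 1) with 1 library left out, with 13 without aged vehicle 1 and 14 without aged vehicle 3. DESeq2 and voom calls included all 22. The 71 calls of aged SAHA against young vehicle stayed within 57 to 81 with 1 library left out and within 58 to 97 elsewhere, with 80 without the pair.

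Called lists for age numbered 0 with an estimated correlation, 3 with fry and 3 to 5 with 1 library left out (5 in the main setting). For SAHA, 1 list became 0 with an estimated correlation, fry, DESeq2 size factors, only the groups compared, summed arms and the replicate block, and 0 to 2 with 1 library left out (2 without aged vehicle 2). For aged SAHA against young vehicle, 1 list became 0 with an estimated correlation and with the stricter filter, under which the Sfmbt2 list had under 3 tested members, 3 with fry, and 1 to 5 with 1 library left out (5 without aged SAHA 2 or 4).

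The correlation of SAHA with age effects, -0.329, was -0.582 with no filter, -0.278 with the block and -0.499 to -0.245 with 1 library left out, and it was near 0 when the aged vehicle libraries were split (median 0.0557 over 20 splits, from -0.172 to 0.163, with 7 below 0). Differences of library summaries with 1 library left out ranged from -772078 to -311680 total counts for age (exact permutation p 0.00631 without young vehicle 4), -756605 to -296207 for aged SAHA against young vehicle (0.00991 without young vehicle 4) and -13.8 to -5.91 detected miRNAs for age (0.0290 without young vehicle 4). For the percent of the 10 most abundant they ranged from -1.28 to -0.426 for SAHA (0.0190 without aged vehicle 2) and from -1.60 to -1.07 for aged SAHA against young vehicle (0.0513 without aged SAHA 1, 0.0684 without aged SAHA 3).

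With replicate number as a block, age gave 8 calls, all lower (miR-146a-5p had an adjusted p of 0.0926), SAHA 15 and aged SAHA against young vehicle 58. The numbers do not pair the libraries: residual r of libraries with the same number ran from -0.317 to 0.271, -0.199 to 0.109 and -0.114 to 0.314 in the 3 comparisons, with 1 of 5, 1 of 5 and 2 of 6 pairs above 0.1. Over 93 named results, each a miRNA in 1 comparison, 2096 alternatives were run: 1903 kept direction and side of the threshold, 132 lost the call, 47 gained one and 14, all of results not called, changed sign. Of 64 that were called, 41 passed in every alternative run. On simulated data with 200 of 509 miRNAs changed, the SAHA comparison recovered 41% of the smallest changes added, and depth itself was not varied.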

Other observations

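The tests on the arms of a precursor were chosen only after the result was seen, as was the choice of miRNAs named here.

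Beyond single directions, fry's test for change either way marked 3 lists for age: brain ageing literature (adjusted p 0.000137), synaptic plasticity and memory (0.000656) and the miR-181 family (0.00915). For SAHA it marked 5, namely the let-7 family (0.00187), neuron-enriched miRNAs (0.00713), the Dlk1-Dio3 cluster (0.0142), the miR-17-92 and paralogous clusters (0.0179) and the miR-30 family (0.0252). In aged SAHA against young vehicle it marked 9: brain ageing literature (4.51e-06), neuron-enriched (1.04e-05), let-7 (2.31e-05), microglia and immune (3.59e-05), Dlk1-Dio3 (0.000315), mirtrons (0.0008), miR-17-92 (0.0136), miR-181 (0.0311) and Sfmbt2 (0.0329). This test compares no list with other miRNAs. Camera, which does, called the miR-181 family for age, the neuron-enriched list for SAHA and Sfmbt2 in the last comparison among these, with adjusted p = 0.588, 0.936 and 0.626 with an estimated correlation. In the miR-17-92 paralogs miR-106b-5p rose under SAHA (0.38 ± 0.09), and its neighbour miR-93-5p rose in aged SAHA against young vehicle (0.34 ± 0.08, from 424 to 535 CPM, adjusted p 0.00393 by edgeR, above the young mean in 6 of 6 libraries). miR-181d-5p, from the precursor next to Mir181c, fell in aged SAHA against young vehicle (-0.29 ± 0.05, adjusted p 0.000578, below all 8 young libraries in 6 of 6).

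In aged SAHA against young vehicle, 21 of the 26 tested neuron-enriched miRNAs had negative values (median -0.12), with 3 lower and 1 higher over all tested and 4 lower and 1 higher when adjusted over the list alone. In the same comparison 6 of 7 oligodendrocyte miRNAs (median 0.38) and 8 of 10 microglia and immune miRNAs (median 0.40) had positive values, and the neuron scores of aged SAHA 1 (-0.20) and aged SAHA 3 (-0.23) were the lowest of the 19 libraries. miR-128-3p (-0.46 ± 0.08), miR-153-5p (-0.40 ± 0.10) and miR-9-3p (-0.24 ± 0.06) fell, and miR-488-3p rose (0.23 ± 0.07, adjusted p 0.0417). The call of miR-488-3p ended without young vehicle 1, 2, 4, 7 or 8 or aged SAHA 2, 4, 5 or 6 (highest adjusted p 0.0907), and that of miR-9-3p ended with library size alone (0.05002). The neuron-enriched list had a camera adjusted p of 0.112 there. Of the 44 lower calls of that comparison, 9 were in the Dlk1-Dio3 cluster where 7.09 were expected (Fisher's exact test, two-sided p = 0.395), miR-127-3p (-0.32 ± 0.06) among them.

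A hypothesis is that both arms of a precursor follow its amount, so that their fold changes move together. Across 292 tested miRNAs that are the 2 arms of 1 precursor each, the arms' log2 fold changes had a Pearson r of 0.487 and a rho of 0.411 for age, above the 0.139 that 95% of random pairings stayed under (permutation p = 1e-05, the smallest that the permutations can give, adjusted 1.5e-05 over 3 tests). For SAHA r was 0.0663 and rho 0.0345, below the 0.136 of random pairings (permutation p = 0.425), so these data do not show the arms moving together in that comparison. For aged SAHA against young vehicle r was 0.513 and rho 0.395, above the 0.136 of random pairings (permutation p = 1e-05, again the smallest possible, adjusted 1.5e-05). Precursors are not independent replicates, whether r differs between the comparisons was not tested, and shared noise of both arms within a library would also raise r. Among these precursors 1 had arms called in opposite directions under SAHA, that of let-7d, and it did so in aged SAHA against young vehicle as well (0.28 ± 0.07 for let-7d-5p and -0.35 ± 0.08 for let-7d-3p).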
